A study of Mus musculus with 6 samples.

How the data were processed

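H3K27ac HiChIP was done on 6 samples, 2 replicates each of mouse TSC, XEN and EPISC cells, with the Arima-HiC+ kit per the labels' protocols. ESC, which a protocol mentions, were not analysed here. Per the submitters' processing notes, HiC-Pro 3.0.0 was used with the mm10 genome. The loop caller, its thresholds and the way the replicates were combined are not given in the sources used here. The samples' descriptions name 1 file per line, so replicates could not be separated and no spread between them could be measured.

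Each row of a deposited list gives a pair of bins of 5 kb and a value. In the TSC list the deposited value is a whole-number count of contacts. In the XEN and EPISC lists the deposited signal is, for 100% of rows, a whole multiple of a single step, 0.563 and 0.517, to within 0.000888 and 0.000952 of a step, so that it appears to be a contact count multiplied by a factor that the authors do not state. Values were divided by that step to give contacts. Only called loops are listed, so a loop missing from a list had not been called and its contacts are unknown. The smallest number of contacts was 5 in TSC, 6 in XEN and 2 in EPISC. Loops spanned at least 10 kb and less than 2 Mb. Depth is known only as the contacts within called loops, and a longer list can reflect deeper sequencing. Loop numbers were therefore not compared as biology, and gene values were given as rates per 10000 loops of the list.

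The groups were the 3 lines, each with 1 list. A loop was called shared when both anchors overlapped both anchors of a loop in the other list. All lists use the same bins, so this required identical bins. Chance was taken from 100 lists shifted at random within their chromosomes. An anchor without a shared partner was one present in both lists of a pair with no loop in common. A promoter loop of a gene had a start site of a protein-coding transcript in an anchor, from GENCODE M21 for GRCm38, which has the coordinates of mm10. Every anchor lay within the lengths of the chromosomes of that assembly. Genes that share a bin cannot be told apart at this resolution. Of the 21800 genes used, those with at least 3 loops over the 3 lists, 9845 genes, had a line share. The median share of each of 16 gene lists was placed among 10000 random lists of the same size drawn from 10 classes of summed rate, and was said to stand apart when outside the central 95%. The percentile describes these lists and is not a test between lines. The imprinted list was measured for 13 of 15 genes, since 2 are not protein-coding.

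The design, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule took, for each lineage list, the 8 markers with most loops in their own line and every marker with a share under 33.3%, then the 8 other genes with the largest excess rate in each line, up to 3 genes from each other list, and the 5 genes with most loops in all 3 lists. Further members of the fixed lists were named as examples after their values were seen. The design allowed for a q-value per loop, but the files give contacts only, so the stronger loops were taken by contacts, which favours short loops. For that reason equal numbers of loops of each length were added as an alternative after the data were seen, as were the same numbers drawn at random, the FGF and MAPK list without Fgfr2, and the use of the 5' end of each gene alone. The other alternatives were wider anchors, the stronger part of each list, equal list length, loops over 100 kb, autosomes, wider promoters, all annotated genes, rates per promoter loop, at least 1 loop per gene and weighting by contacts.

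The measures were tested on simulated data. Known shares of the real lists, kept in identical bins, were recovered within 0.634 percentage points. Kept loops match by construction, so only accidental matches of moved loops could open a gap. Of 300 anchors given new partners, 100% were found, but those partners lay farther off than any real loop reaches, which fixed this outcome in advance. No loop was moved to a neighbouring bin, so the simulation does not show how such small shifts affect the measures. Of 100 random lists of 17 genes, 5 stood apart with no change, 97 with rates raised by a factor of 2 in TSC and 100 with a factor of 4. Shares carry exact binomial intervals at the 95% level, which cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.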

Results

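H3K27ac HiChIP was measured in 3 mouse stem cell lines. The method joins DNA ends that lie close together in the nucleus and then enriches the joined fragments with an antibody against acetylated lysine 27 of histone H3, a mark of active promoters and enhancers. The lines were trophoblast stem cells (TSC), XEN cells, which the labels call extraembryonic stem cells, and EPISC, which they call epiblast-like stem cells. They stand for the placental, yolk sac and embryo-forming lineages of the early mouse embryo. Each line had 2 replicates, and the deposited data gave 1 pooled list of loops per line, a loop being a pair of 5 kb bins in contact. The TSC list held 60909 loops with 1649998 contacts in all, the XEN list 77124 loops with 2131868 contacts and the EPISC list 50618 loops with 1156654 contacts. The median loop had 20, 20 and 16 contacts. Since each line had a single pooled list, no difference between lines had a replicate check, and no p-value is given. The intervals cover counting error only, and treat loops as independent although neighbouring bins often belong to 1 contact. Loop counts and rates are likewise of pairs of bins, and not of separate contacts.

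The design asked how enhancer contacts differ between these lineages. In the XEN list, several genes of extraembryonic endoderm held loops that were rare or missing in the other lists, while others also had loops in TSC. Gata6, a transcription factor that specifies primitive endoderm (chromosome 18, 11052064 to 11085635, mm10), had 34 promoter loops in the XEN list, 1 in the TSC list and 0 in the EPISC list. Gata4, its close relative, had 39, 10 and 0. Sox17 and Foxa2, transcription factors of endoderm, had 27 and 32 XEN loops and none in the other lists. Pdgfra, a growth factor receptor on primitive endoderm cells, had 40 in XEN, 7 in TSC and 0 in EPISC. Of the 25 markers fixed in advance, 21 had at least 3 loops over the 3 lists. In 16 of these the number of loops per 10000 loops of the list, the rate, was highest in XEN, and 9 had loops in the XEN list only. Of all 25, 12 had a loop in the TSC list and 5 in the EPISC list. The line share of a gene is its rate in 1 list divided by the sum of its 3 rates, so that equal rates give 33.3%. The median XEN share was 81.9%, above all 10000 random lists of genes with similar rates. Other genes with loops in the XEN list only were Srgn with 25, Dab2 with 16, Hnf1b with 15 and Sox7 with 14. Foxq1 had 32 XEN loops and none elsewhere, but it shares its promoter bin with A530084C06Rik, and the loops cannot be divided between them. Col4a1 and Col4a2, collagen IV genes of the basement membrane that share a promoter bin, had 30 XEN and 17 TSC loops, a higher rate in XEN that turned when only the stronger loops of each list were kept. The other 5 markers had their highest rate in TSC. They were Sparc with 23, 24 and 17 loops in TSC, XEN and EPISC, Lamb1 with 16, 19 and 5, Thbd with 16, 13 and 1, Lamc1 with 12, 9 and 4, and Snai1 with 10, 7 and 1. Sparc had its highest rate in XEN in 3 alternative settings and Snai1 in 2, and the alternatives were not run for Lamb1 and Thbd. Hnf4a, Nid1, Amn and Ttr had no promoter loop in any list.

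Contacts at Gata6 ran mostly upstream of the gene. The strongest XEN loop joined its promoter bin at 11050001 to 11055000 with an intergenic bin at 10945001 to 10950000, 105 kb away, with 122 contacts. The longest spanned 440 kb and ended at the promoter of Esco1. The only TSC loop of Gata6, of 210 kb with 17 contacts, was also in the XEN list. Many of the XEN partners of Gata6 were adjacent bins, such as those from 10815001 to 10875000, so its loops are not separate contacts. The strongest XEN loop of Gata4 (chromosome 14, 63198922 to 63271692) had 495 contacts, and ended 10 kb from the promoter bin inside the gene. At Sox17 (chromosome 1, 4490931 to 4497354) the strongest loop reached an intergenic bin at 4535001 to 4540000 with 75 contacts.

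**Figure D1:**
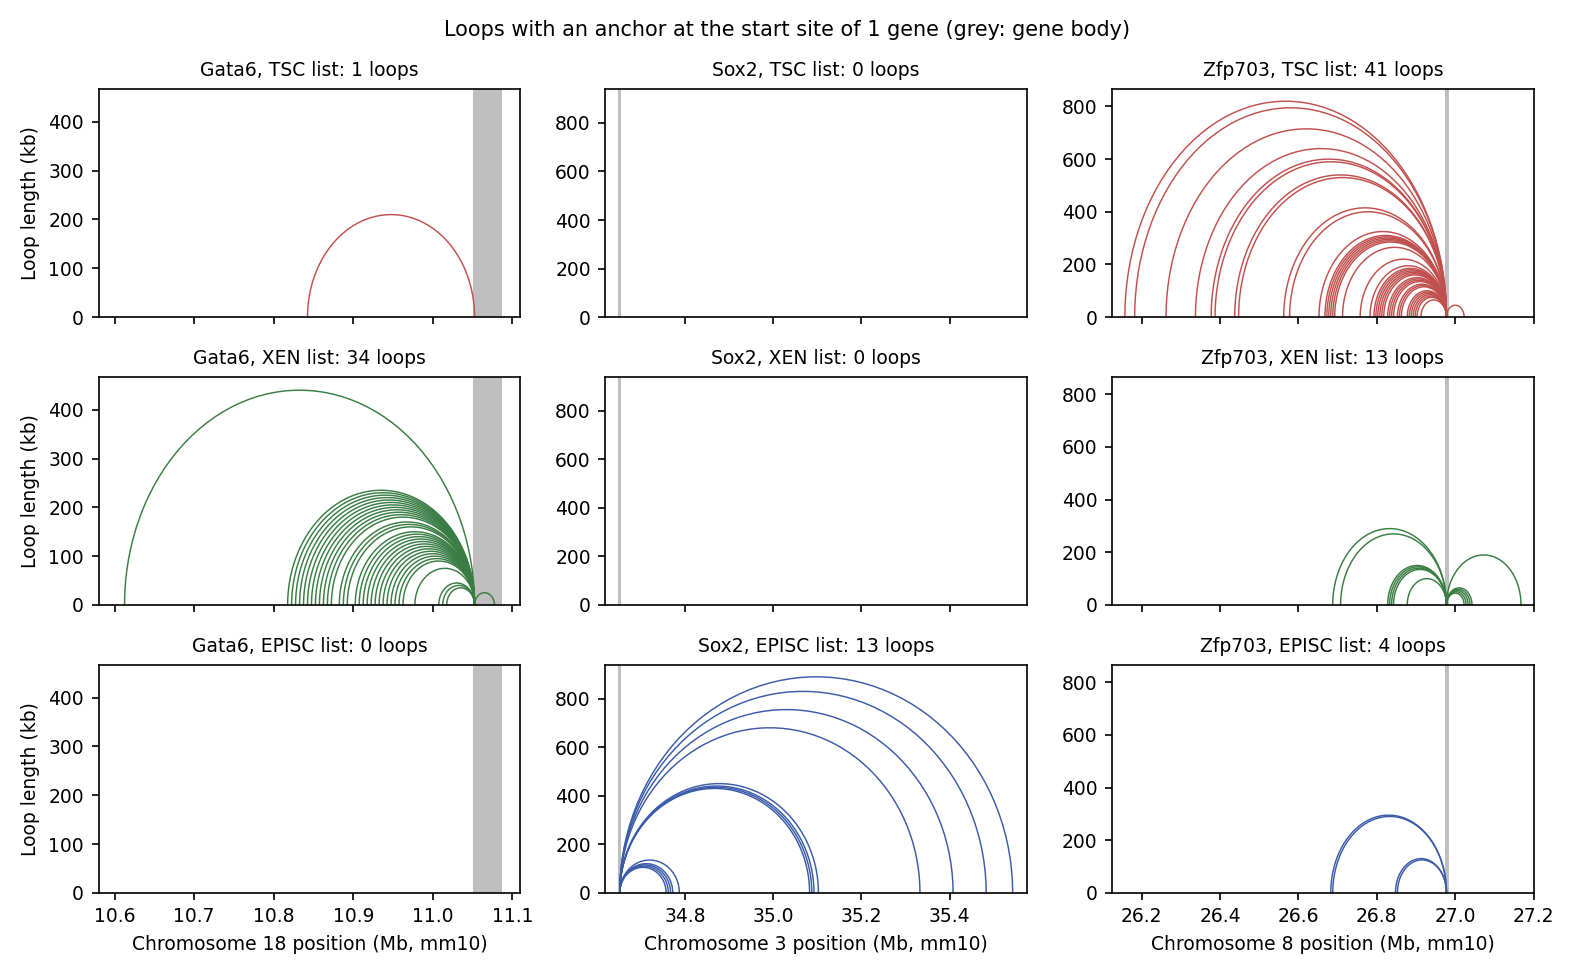
Loops with an anchor in a start-site bin of Gata6, Sox2 or Zfp703, drawn as arcs along the chromosome in Mb (mm10) with loop length in kb as height. Each row is 1 loop list and the grey band is the gene body. Gata6 had 34 loops in the XEN list, Sox2 had 13 in the EPISC list and none in the others, and Zfp703 had 41, 13 and 4 in the TSC, XEN and EPISC lists.

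Markers of epiblast and primed pluripotency held their loops largely in the EPISC list. Sox2, a core pluripotency transcription factor (chromosome 3, 34650405 to 34652461), had 13 EPISC loops and 0 in both other lists. The same held for Nodal with 8, Tdgf1, a co-receptor of Nodal, with 8, Fgf8 with 7 and Otx2 with 5. Zic2, a zinc finger transcription factor of the epiblast, had 17 EPISC loops against 1 in TSC and 2 in XEN. Of the 25 markers, 16 had at least 3 loops, 14 of these had their highest rate in EPISC and 8 had loops there only. Their median EPISC share was 94.4%, above all 10000 random lists. Pou5f1 and Nanog, core pluripotency genes, had few loops, 5 and 2 in EPISC, with 1 Pou5f1 loop in XEN. Sall4, with 17, 13 and 14 loops in TSC, XEN and EPISC, and Dnmt3b, with 3, 3 and 2, had their highest rates in TSC, by small margins that turned to EPISC in 2 alternative settings each. The Sox2 loops all ran downstream. The strongest reached an intergenic bin at 34755001 to 34760000 with 22 contacts, 105 kb from the promoter bin, and the longest spanned 890 kb.

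Among the markers of trophoblast stem cells, Zfp703 (chromosome 8, 26977325 to 26981461) had 41 TSC loops, 13 in XEN and 4 in EPISC. Tfap2c, a transcription factor of trophoblast (chromosome 2, 172549593 to 172558622), had 13 TSC loops and none in the other lists, and Hand1, with 9, and Krt7, with 7, were also confined to the TSC list. Ets2 had 19, 8 and 1, and Wnt7b had 15, 4 and 1. Of the 25 markers, 17 had at least 3 loops, 13 of these had their highest rate in TSC and 3 had loops in TSC only. Their median TSC share was 60.1%, above all 10000 random lists, and their median EPISC share, 4.54%, was below all of them. Their median XEN share was 18.3% (percentile 0.22, up to 64.4 in other settings). Tead4, a transcription factor needed for trophoblast specification, had 30 TSC, 25 XEN and 1 EPISC loops, and among loops over 100 kb its rate was higher in XEN. Krt18 and Krt8, keratins of simple epithelia, had loops in every list, at 21, 27 and 9 and at 16, 13 and 8, and the list with their highest rate depended on the setting. Eomes, a regulator of both trophoblast and gastrulation, had 3 TSC and 5 EPISC loops, an order that turned among loops over 100 kb, and Nr2f2 had 5 XEN loops only. Fgfr2 counted 12, 9 and 18 loops, but the annotation gives it a start site in the promoter bin of Ctbp2, so its value cannot be read as that of Fgfr2. Cdx2, the trophoblast master regulator, had 2 TSC loops, Elf5 had 1, and Esrrb, Tfap2a, Bmp4 and Ascl2 had none in any list.

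**Figure D2:**
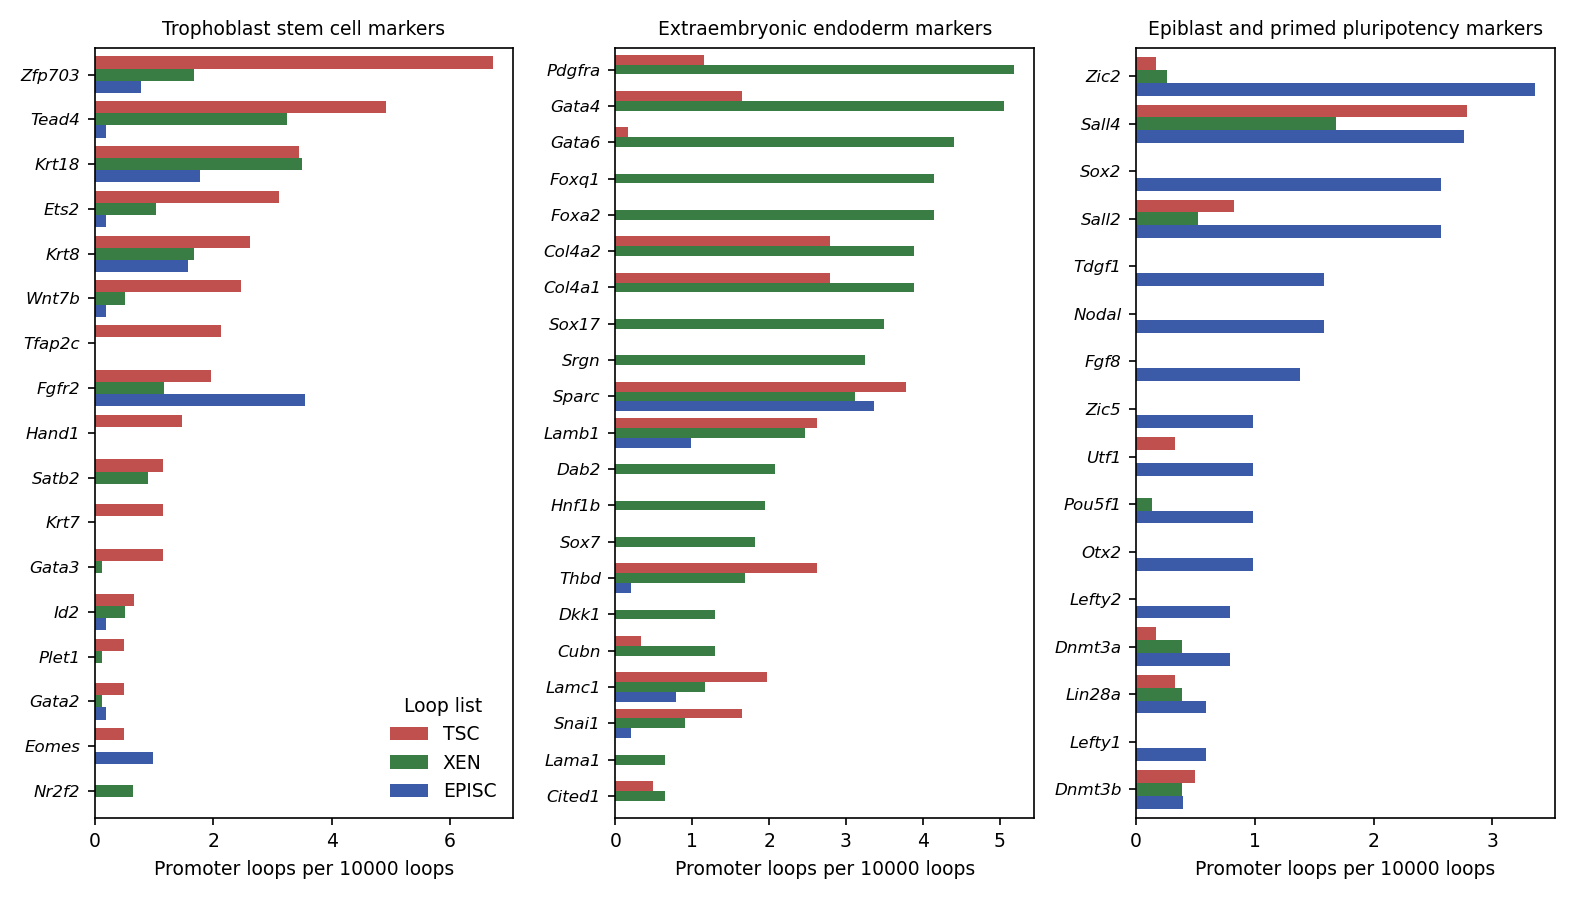
Promoter loops per 10000 loops of the list (horizontal axis) for each marker with at least 3 loops over the 3 lists, with 1 panel per marker list and 1 bar per loop list. XEN bars lead in 16 of 21 endoderm markers, EPISC bars in 14 of 16 epiblast markers and TSC bars in 13 of 17 trophoblast markers.

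Among the 13 other gene lists, FGF and MAPK pathway genes leaned to EPISC, with a median EPISC share of 53.1% (percentile 99.99 of the random lists) and 11 of 15 genes at their highest rate there. The median gene was Fgfr2, whose loops are those of the Ctbp2 bin. Without it the median was 55.0% (percentile 99.99), and 10 of 14 genes had their highest rate in EPISC. Dusp6, a phosphatase induced by ERK signalling, had 34 EPISC loops against 8 in TSC and 3 in XEN, Etv5 had 12 against 3 and 6, and Spred1 had 10 against 2 and 3. Egr1 and Fos went the other way, with 31 and 26 loops in TSC and 7 and 14 in EPISC. Dusp4 had 30 EPISC, 20 TSC and 26 XEN loops, a lead that was lost when the stronger loops alone were kept or with equal numbers of each length. Imprinted genes leaned to TSC, with a median TSC share of 54.0% over 8 of 13 measured genes (percentile 99.97). Of these 8, 6 had their highest rate in TSC. Igf2, a fetal growth factor, had 18 TSC loops and none elsewhere, and Peg10, needed for placental development, had 18, 4 and 1. Igf2 shares promoter bins with Gm49394, and its lead fell from 2.96 to 0.493 loops per 10000 when only the 5' end was used. Peg10 shares its bin with Sgce, and its strongest loop in each list ended in the body of Sgce, so these loops cannot be credited to Igf2 or Peg10 alone. Phlda2 and Cdkn1c, with 6 and 4 EPISC loops against 0 and 2 in TSC, did not follow. In other settings the percentile of the imprinted list was as low as 96.1. Visceral endoderm and liver-type genes had a median XEN share of 63.3% over 7 of 15 genes (percentile 99.85). Of these 7, Apoa4 alone, with 1 TSC and 3 EPISC loops, did not have its highest rate in XEN. Cyp26a1, an enzyme that degrades retinoic acid, had 19 XEN loops against 2 in TSC and 0 in EPISC, and Apoe had 12, 3 and 5 in XEN, TSC and EPISC.

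Gastrulation and mesendoderm genes had a median EPISC share of 61.5% over 6 of 15 genes (percentile 97.9, as low as 87.9 in other settings). Foxh1, a partner of Smad proteins, had 11 EPISC and 2 TSC loops, and Wnt3 had 6 EPISC loops only. T, Mixl1, Gsc and Mesp1 were among the genes of this list with no loop in any line. Of the 6 genes, 4 had their highest rate in EPISC, while Tbx6, with 3 XEN loops and 1 in EPISC, and Fst, with 5 and 1, led in XEN. Naive pluripotency genes had a median TSC share of 53.9% over 5 of 15 genes (percentile 99.6), and 4 of these 5 had their highest rate in TSC. Zfp42, Prdm14, Nr5a2 and Dppa3 were among the genes of this list with no loop in any line. Among these 4 was Tbx3, with 7, 6 and 0 loops in TSC, XEN and EPISC. Klf4, with 4, 8 and 0, had its highest rate in XEN. Both genes changed their leading line among loops over 100 kb. Genes of the TGF-beta, Nodal and BMP pathways were low in EPISC, with a median share of 18.3% (percentile 0.33, up to 14.4 in other settings). Of 13 genes, 7 had their highest rate in XEN, 4 in TSC and 2 in EPISC. Id3, a target of BMP signalling, had 18 XEN loops against 3 in TSC and 2 in EPISC, Smad2 had 22, 8 and 2, and Smad7 had 44 loops in TSC, 31 in XEN and 19 in EPISC. The genes that led in EPISC were Skil, with 3, 5 and 7 loops in TSC, XEN and EPISC, and Bmpr1a, with 19, 20 and 20. Median shares were also low for the FGF and MAPK list in XEN (21.4%, percentile 1.12), the imprinted list in XEN (7.06%, 0.16) and EPISC (18.0%, 2.26), and in TSC the gastrulation (6.56%, 1.89) and visceral endoderm lists (16.2%, 2.22), but none of these stayed outside the central 95% of random lists in every setting. Wnt and Hippo pathway genes did not stand apart, with median EPISC shares of 46.4% and 34.6% (percentiles 96.4 and 56.1), although other settings gave percentiles up to 99.1 for the Wnt list and down to 2.18 for the Hippo list. Ankrd1, a target of Hippo signalling, had 19 XEN loops, 1 in TSC and 0 in EPISC. Housekeeping genes had median shares of 32.4%, 29.2% and 33.4% in TSC, XEN and EPISC, near those of random lists. Genes of cell types not studied here had few loops. Of 15 neural genes, 1 had at least 3 loops (Tubb3, with 3, 2 and 1), and of 15 blood and muscle genes only Runx1 did, with 5, 22 and 3. Pcdh12, with 3 TSC loops, was the only differentiated trophoblast gene to reach that number. Of 15 fibroblast genes, 4 had a TSC loop, 0 a XEN loop and 1 an EPISC loop. Their median TSC share was 100% over the 3 genes with at least 3 loops (percentile 99.88, down to 95.6 in other settings).

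Outside the marker lists, the genes with the largest excess in TSC included Lpp, which encodes an adhesion protein (70, 23 and 23 loops in TSC, XEN and EPISC), Mbnl2, a splicing regulator (49, 16 and 9), Jun (112, 51 and 67), Fosl2 (59, 40 and 29) and Basp1 (24, 1 and 2). Jun and Fosl2 encode subunits of the AP-1 transcription factor. In XEN they included Pcgf5, a Polycomb subunit (68 XEN, 28 TSC and 0 EPISC loops), Rela, an NF-kB subunit (59, 21 and 18), Mxi1, an antagonist of Myc (44, 13 and 5), Ddah1 (34, 5 and 1) and Adora1 (25, 0 and 0). Bcl6 (71, 25 and 30), which shares a promoter bin with Gm37419, lost its lead at equal list length. Adcy6 (34, 1 and 2) owed its loops to a start site inside the gene and lost its lead when only the 5' end was used. In EPISC they included Phc1, another Polycomb subunit (37 EPISC, 4 TSC and 4 XEN loops), Dusp6, the chromatin remodeller Chd9 (25, 1 and 0) and the histone gene Hist1h2ag (29, 6 and 8), which shares its promoter bin with Hist1h2bj and Hist1h4i. Bscl2 and Gng3, which share promoter bins, had 40 and 31 EPISC loops. At Phc1 (chromosome 6, 122317731 to 122340561) the strongest EPISC loop had 181 contacts and reached an intergenic bin 25 kb away.

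Loops were shared between lists far more often than with lists shifted at random. Of the TSC loops, 42.9% (95% exact binomial interval 42.5 to 43.3) were in the XEN list and 29.0% (28.6 to 29.3) in the EPISC list. Of the XEN loops, 33.9% were in the TSC list and 20.7% in the EPISC list. Of the EPISC loops, 34.9% were in the TSC list and 31.5% in the XEN list. Lists shifted at random along the chromosomes matched 0.231% to 0.445% of loops on average. The shifts move anchors away from promoters, so this gap does not show sharing beyond what common promoters give. Counted over both lists of a pair, TSC and XEN shared 37.9%, TSC and EPISC 31.7% and XEN and EPISC 24.9%. With anchors widened by 5 kb these shares were 59.4%, 52.2% and 42.7%. XEN and EPISC shared least in every setting tried. When lists were thinned at random to 45902 loops each, an alternative chosen after seeing the data, TSC and XEN shared 25.5% and TSC and EPISC 26.4%, but this removes more of the longer XEN list than of the EPISC list and so lowers the TSC and XEN value most.

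A set of 11406 loops was in all 3 lists. It included 46 loops at Ywhaz, a 14-3-3 protein gene used as a housekeeping reference, 30 at Plec, 24 at Arid2, a chromatin remodelling subunit, and 24 at the bin shared by Hnrnpk and Rmi1. Loops found in 1 list only made up 46.8% of the TSC list (SD over 19 autosomes 3.62), 60.2% of the XEN list (4.63) and 56.2% of the EPISC list (4.25). The TSC share was lower than both others on all 19 autosomes, which come from the same pooled lists and are not replicates. With anchors widened by 5 kb the shares were 25.4%, 38.7% and 36.7%. XEN and EPISC changed places at equal list length, where 53.7% of XEN and 63.8% of EPISC loops were in 1 list only. That setting kept every EPISC loop and dropped the weakest loops of the other lists, which can only raise the EPISC share. In every list the loops of 1 list only were weaker than those in all 3 lists. Their median contacts were 17 against 27 in TSC, 17 against 28 in XEN and 14 against 24 in EPISC.

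**Figure D3:**
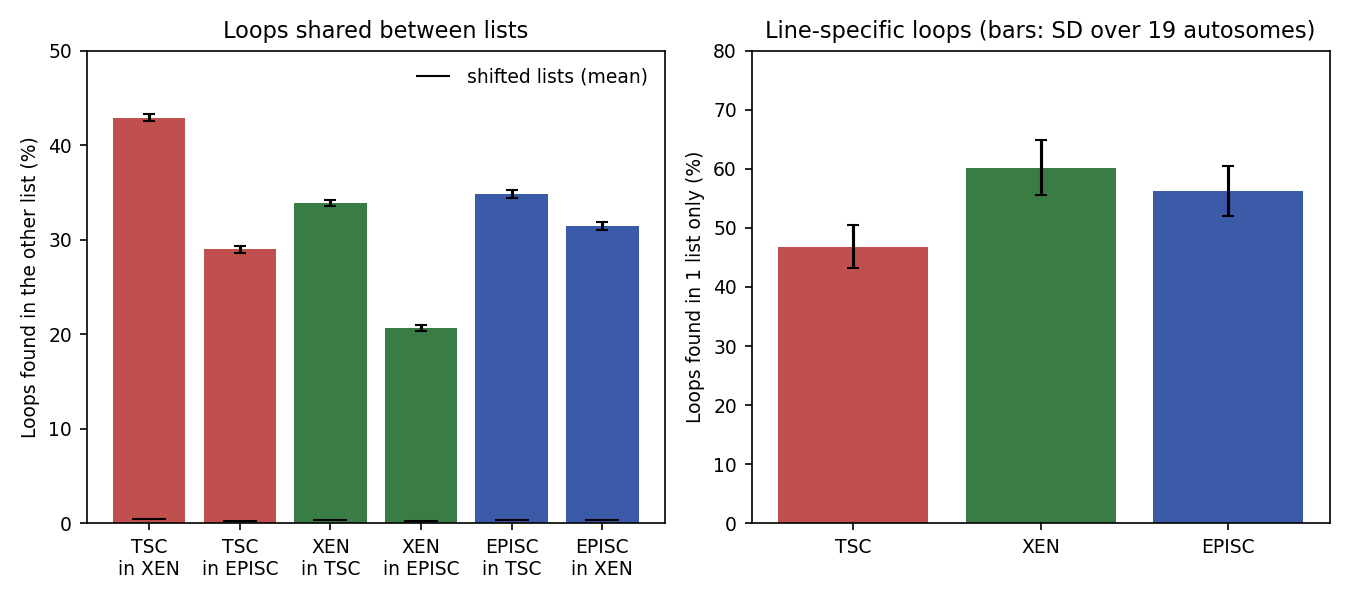
Left, share of each list's loops (%) found in another list, with 95% exact binomial intervals and, as black lines near 0, the mean over 100 randomly shifted lists. Right, share of loops found in 1 list only (%), with the SD over 19 autosomes as error bars. TSC has the lowest share of its own, 46.8%, against 60.2% in XEN and 56.2% in EPISC.

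Anchors were shared more often than loops. Of the TSC anchors, 72.9% were also anchors in another list, against 66.8% in XEN and 61.2% in EPISC, and 14566 anchors were in all 3. Anchors in both lists of a pair but with no loop in common made up 16.2% for TSC and XEN, 22.5% for TSC and EPISC and 24.4% for XEN and EPISC. With anchors widened by 5 kb these shares were 5.57%, 9.21% and 10.4%, and with equal numbers of each length they were 30.9%, 28.6% and 34.0%. Such anchors mostly had few loops. Among anchors with at least 5 loops in both lists, partners were pooled over both lists, each counted once. At the median anchor 40%, 33.3% and 31.3% of these partners were in both lists. Only 9 of 5165, 19 of 3404 and 25 of 3380 such anchors had no loop in common. Myc, a growth regulator named here after its values were seen, was among these exceptions. Its promoter bin (chromosome 15, 61985001 to 61990000) had 16 XEN and 5 EPISC loops and none in common. The strongest XEN loop ran 185 kb to 62170001 to 62175000 with 46 contacts, and the strongest EPISC loop 105 kb to 62090001 to 62095000 with 19 contacts.

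Promoters of protein-coding genes lay at an anchor of 66.3% of TSC loops, 57.7% of XEN loops and 68.2% of EPISC loops. The share was 83.3% among loops in all 3 lists, and 58.7%, 47.3% and 58.9% among the loops found in the TSC, XEN or EPISC list only. Anchors in all 3 lists held a promoter in 47.5% of cases, against 7.42%, 7.16% and 8.99% of the anchors found in 1 list. In all, 7569 of 21800 genes had a promoter loop in every list, and 577, 766 and 1112 had loops in TSC, XEN or EPISC only.

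Loops were shortest in TSC, with a median of 65 kb, against 90 kb in XEN and 100 kb in EPISC, and 33.4%, 45.0% and 49.0% spanned over 100 kb. The gap between TSC and XEN nearly closed at equal list length, with medians of 50 and 55 kb, and in the stronger part of each list the medians were 30, 40 and 45 kb. Loops in all 3 lists had a median length of 70 kb, while those of 1 list only measured 55 kb in TSC, 100 kb in XEN and 120 kb in EPISC. The 10% of anchors with most loops held 40.1%, 38.2% and 40.1% of loop ends. The Jun promoter bin (chromosome 4, 95050001 to 95055000) had most loops in TSC, 112, and in EPISC, 67, and had 51 in XEN. In XEN the leading anchor, with 92 loops against 40 in TSC and 56 in EPISC, overlapped Hes1, a Notch target (chromosome 16, 30060001 to 30065000). That bin held no start site of a protein-coding transcript, which does not place it away from the Hes1 promoter. An intergenic anchor on the same chromosome, 30500001 to 30505000, had 72 loops in XEN, 44 in TSC and 6 in EPISC.

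The lists were spread unevenly over the autosomes. Chromosome 16 held 5.48% of XEN loops against 3.90% of TSC and 3.65% of EPISC loops, and chromosome 1 held 5.84% against 3.93% and 4.04%. Chromosome 7 held 5.98% of XEN loops against 7.99% in TSC and 7.45% in EPISC. Chromosomes 13 and 17 held 3.96% and 7.0% of EPISC loops, against 3.02% and 5.40% in TSC and 2.86% and 4.99% in XEN.

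**Figure D4:**
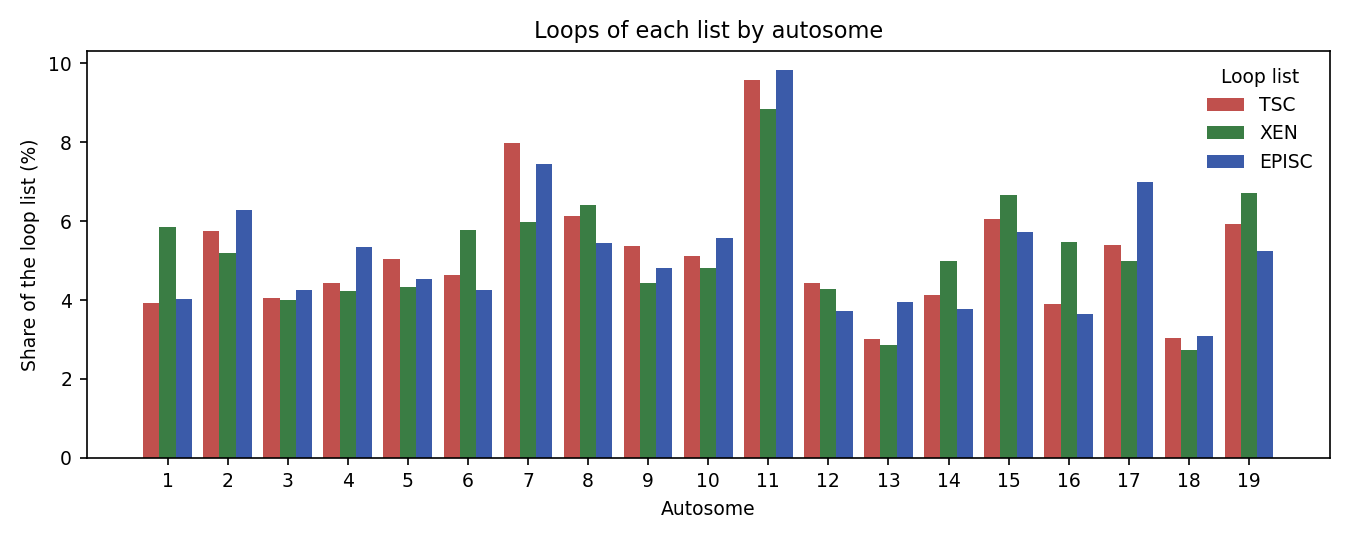
Share of each loop list (%) on each autosome, with 1 bar per list. Measured against the mean of both other lists, XEN bars have their largest ratios on chromosomes 1 (1.47) and 16 (1.45), and EPISC bars on chromosomes 13 and 17 (1.35 on each).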

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

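No paired analysis was possible because the deposited lists pool the replicates, and for the same reason no replicate could be left out. The alternatives chosen after the data were seen were equal numbers of loops of each length, the same numbers drawn at random, the FGF and MAPK list without Fgfr2, and the 5' end of the gene only. The median own-line share of all 3 lineage marker lists stayed above all random lists in every alternative run for them. It was 59.1% to 72.4% for TSC, 70.3% to 100% for XEN and 89.0% to 100% for EPISC. Wider anchors, all annotated genes and the same numbers drawn at random were not run for these lists. Autosomes alone left every value that has an interval within it. The marker medians, which have none, were 60.1%, 89.1% and 94.4%, with 20 endoderm genes where all chromosomes gave 21 and 81.9%. Identical anchors changed nothing by construction. Unless stated, the cause of a change was not tested. Values below are in the order TSC, XEN, EPISC, or TSC with XEN, TSC with EPISC, XEN with EPISC.

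With anchors widened by 5 kb, loops in 1 list only fell to 25.4%, 38.7% and 36.7%, anchors in another list were 86.5%, 81.8% and 74.9%, shared loops 59.4%, 52.2% and 42.7%, and anchors with no loop in common 5.57%, 9.21% and 10.4%. This follows from the wider match. Loops of 1 list were then shorter than shared loops in TSC (a difference of -20.0 kb, against -15.0 kb) and longer in XEN (35.0 kb, against 30.0 kb).

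In the stronger part of each list by contacts, median length was 30, 40 and 45 kb, since strong loops are short. Loops in 1 list only were 42.4%, 57.5% and 54.6%, shared anchors 72.1%, 63.1% and 60.1%, loop ends at the leading 10% of anchors 36.6%, 35.3% and 35.7%, promoter loops 65.9%, 54.8% and 69.4%, shared loops 41.8%, 34.2% and 26.2%, and anchors with no loop in common 11.4%, 17.4% and 18.4%. At equal list length, median length was 50 kb in TSC and 55 kb in XEN, and loops in 1 list only were 53.7% in XEN and 63.8% in EPISC, which reversed their order. Shared anchors were 72.1%, 70.4% and 53.3%, loop ends at the leading anchors 39.1% in TSC and 36.4% in XEN, promoter loops 55.7% in XEN, shared loops 40.8%, 30.7% and 23.9%, and anchors with no loop in common 13.4% for TSC with XEN. Among loops over 100 kb, 41.7%, 65.3% and 64.1% were in 1 list only and 34.6%, 28.3% and 22.1% were shared.

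With equal numbers of each length, loops in 1 list only were 56.9%, 64.7% and 63.8%, shared loops 26.6%, 27.5% and 19.7%, and anchors with no loop in common 30.9%, 28.6% and 34.0%. The same numbers drawn at random without matching lengths gave 58.3%, 66.0% and 65.1%, then 25.5%, 26.4% and 18.7%, and 30.4%, 29.0% and 35.8%. The turned order of the first pairs thus also appears without matching lengths, and follows from thinning lists of unequal length, which lowers TSC with XEN most. With lengths matched, shared anchors were 70.7% in TSC and 57.8% in EPISC, promoter loops 67.5% in TSC, and loop ends at the leading anchors 34.4% in XEN and 38.6% in EPISC. Promoter loops were 80.3%, 73.8% and 82.0% with start sites within 5 kb, 73.3%, 65.4% and 75.4% with all annotated genes, and 60.3%, 52.6% and 62.6% with the 5' end only, by construction of wider or narrower promoters.

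For 92 gene and line pairs named by the rule, 6 alternatives gave 533 values of the lead of a gene's rate over the larger other rate, and 19 gave none, since no loop was left. The lead stayed within its counting interval in 416 values, moved in 83 and changed sign in 34. The 34 follow, in loops per 10000. In the stronger part of each list they were Krt18 1.17, Col4a1 and Col4a2 -0.0674, Sparc 0.918, Sall4 0.144, Dnmt3b 0.134, Bcl6 -0.0245, Dusp4 -1.15 and Amotl2 -1.73. At equal list length they were Bcl6 -2.77 and Ywhaz -0.198. Among loops over 100 kb they were Tead4 -0.134, Eomes 0.0882, Snai1 0.0844, Tbx3 -0.0844, Klf4 -0.526, Gapdh -0.345, Ywhaz -5.41 and Tcf7l2 -2.27. With equal numbers of each length they were Krt18 0.218, Krt8 -0.218, Sall4 0.436, Tubb3 -0.218, Ywhaz -0.654 and Dusp4 -0.218. With start sites within 5 kb they were Krt18 0.594, Sparc 0.789, Snai1 0.0876, Dnmt3b 0.0695 and Gfap -0.0307. With the 5' end only they were Sparc 0.579, Adcy6 -0.796, Gfap -0.228 and Ywhaz -0.580.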

Other observations

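Tests or settings chosen only after the result was seen were the gene families, the fibroblast test, the AP-2, AP-1 and TEAD motifs, the reordered motifs, and the scale of contacts in the strong-loop test, whose prediction named none. Of 18 gene families picked by symbol, histone genes had a median EPISC share of 66.3% over 61 genes, above all random lists, with TSC and XEN shares, 20.3% and 13.4%, below all of them, and 738 promoter loops in EPISC, 283 in TSC and 282 in XEN. These genes sit in clusters and share 34 promoter bins, so neighbours are not independent. The EPISC share was also high for protocadherins (52.0% over 16 genes, percentile 99.6), Cdk genes (43.1% over 21, 98.8), Kdm genes (44.7% over 14, 98.0) and the 4 Fgf genes with enough loops (88.5%, 99.99), whose TSC and XEN shares were low (6.41%, 0.32, and 5.06%, 0.915). The XEN share was high for Fox genes (42.2% over 17, 99.8), solute carriers (34.6% over 164, 99.94) and keratins (45.5% over 8, 98.1), and low for Wnt genes (5.85% over 8, 0.77). Smad genes had a high TSC share (45.5% over 7, 97.8). The EPISC share was low for keratins (0%, percentile 0.03), Smad genes (18.3%, 1.72) and solute carriers (30.4%, 2.3). With 18 families and 3 lines, some pass this limit by chance. Ribosomal protein genes, with shares of 34.1%, 29.3% and 36.4% in TSC, XEN and EPISC, did not stand apart. On chromosome Y there were 10 loops in the TSC list, 4 in EPISC and 0 in XEN. Among anchors without a promoter found in 1 list only, the AP-2 motif was in 8.94% of TSC, 6.51% of XEN and 7.49% of EPISC anchors, AP-1 in 64.0%, 61.3% and 61.6%, and TEAD in 22.8%, 22.8% and 20.7%. Anchors without a promoter found in all 3 lists held them in 9.35%, 63.3% and 22.9% of cases. AP-2 was thus no rarer there than in anchors of TSC only. Each motif was set against other orders of its letters that share no run of 4 letters with it and have as many CG. For AP-2 the ratio of TSC to the higher other list, 1.19, was above all 139 orders (up to 1.18). For AP-1 it was 1.04, and 9 of 349 orders reached it. For TEAD it was 1.0, and 91 of 413 did. With several motifs and lines tried after the fact, these values settle no cause.

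Loops found in 1 list only could reflect lower depth or stricter calling of the other lists, so strong loops, with at least 2 times the median contacts of the other list's loops of that length, were looked up there within 1 bin. No match was found in the EPISC list for 25.9% of TSC and 48.7% of XEN strong loops. In the XEN list 3.96% of TSC strong loops had none, as depth or calling would give. The other pairs lay between, at 20.3% of XEN loops missing from TSC and 9.62% and 16% of EPISC loops missing from TSC and XEN. To count against depth or calling, the limit set in advance had to be passed in every pair, which was not met. Lower depth or stricter calling thus stays open, also for the EPISC list, which had the fewest contacts and whose calling thresholds are unknown. The values also depend on the scale. On the deposited values 14.6% of TSC loops were missing from XEN and 41.1% from EPISC, 17.1% and 49.5% of XEN loops from TSC and EPISC, and 4.71% (95% interval 2.18 to 8.76) and 13.6% of EPISC loops from TSC and XEN. After scaling lists at shared loops these were 4.98%, 25.5%, 19.6%, 47.5%, 9.86% and 17.8%. Different lineage transcription factors may also act at anchors of 1 line, and the GATA motif AGATAAG was in 53.5% (95% interval 52.6 to 54.4) of XEN-only anchors without a promoter, against 47.7% of TSC-only and 48.8% of EPISC-only anchors. The same letters scrambled as GAAGATA were also most frequent in XEN-only anchors, at 52.7% against 48.7% and 50.1%, but this order keeps the run AGATA and is no clean control. Against 75 orders without such a run, the ratio of XEN to the higher other list, 1.097, was above all of them (up to 1.048). The explanation stays open, since the prediction also asked for the Oct-Sox composite, and its intervals, at 0.221% of EPISC-only and 0.163% of XEN-only anchors, overlapped.

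In 9 cases an autosome's share of a list lay beyond the ratio to the other lists set in advance, with the largest ratios for XEN on chromosomes 1 (1.47) and 16 (1.45). Extra or missing chromosome copies could give this, and would shift the contacts of shared loops along the whole chromosome against both other lists, which was met in 0 of 9. Copies stay open for chromosome 16 of XEN. There these contacts, relative to the other chromosomes, were 1.254 times those of TSC and 1.32 times those of EPISC. Among the loops nearer its start they were only 1.24 and 1.2 times. In 2 of 9, XEN and TSC on chromosome 1, contacts were close to the other chromosomes, at the limit set for this. Both cases use the ratio of XEN to TSC, which was uneven, at 0.981 nearer the start and 1.20 farther along. The 9 cases are not separate, since a change in 1 list moves the ratios of the others. A few loop-rich regions could also give such uneven shares. The 5 windows of 1 Mb with the largest excess were left out, or with the largest deficit for a low share. By construction this tends to move such a ratio toward 1, and can move it past 1, as for XEN on chromosome 14 (1.27 to 0.990). It left 2 of 9 past the ratio set in advance, chromosomes 16 (1.27) and 1 (1.26) of XEN. No biological explanation was tested.

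Feeder fibroblasts among the TSC cells are a candidate source of the fibroblast gene loops in the TSC list. The list stood apart in TSC, with a median share of 100% over 3 genes (percentile 99.88), and of its 15 genes 4 had a TSC promoter loop: Col1a1 and Pdgfrb with 3 each, and Thy1 and Tagln with 1 each. Col1a2 and Col3a1, abundant in fibroblasts, had 0 loops, Tagln had 3 EPISC loops and no fibroblast gene had a XEN loop. With so few loops, feeders and trophoblast cells that use these genes cannot be told apart.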
